A study of Mus musculus with 76 samples.

How the data were processed

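Whole-transcriptome probe counts were measured on brain sections of control mice and of mice with mutations in both Flna and Flnb, called FlnKO, with the GeoMx Digital Spatial Profiler. In this assay barcoded oligonucleotide probes bind RNA in a fixed section, the barcodes are released by light from a chosen region, and the released barcodes are sequenced. Per the labels' protocols, the brains came from mice aged 3 months, with 3 animals per genotype, were fixed by perfusion, and were cut into cryosections of 7 µm. Regions were chosen after staining with antibodies to NeuN and Gfap, so Rbfox3, which encodes NeuN, and Gfap are no finding between regions. The 76 regions fall into 5 groups, which were taken from each region's genotype and region labels. These are 16 regions of periventricular heterotopia (PH, a mass of misplaced neurons beside the ventricle) in FlnKO mice, 13 of FlnKO cortex, 15 of FlnKO VSVZ, 16 of control VSVZ and 16 of control cortex. The labels give the tissue names as PH, Cx and VSVZ, and they do not tie regions to animals. For heterotopia regions 15 and 16 the title names no tissue, and the region label alone gave PH. Each group holds more regions than animals, so some regions share an animal and p-values over regions are too small.

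The deposited count files hold whole-number counts per probe and region, made by the authors with the GeoMx NGS Pipeline 2.3.3.10 per the file headers. The genome build was mm10 per the submitters' processing notes. A further deposited table holds normalised signal values per gene and region. From its values, each signal is the count minus a constant, with a floor of 1, times a factor for each region, and the 75th percentile of every region is 18.272. The constant lay within 1.712% of the geometric mean of the region's 210 negative probes, which match no transcript. This account of the table by the authors was inferred from the values and is stated in no label or header used here. The count files name no genes. Gene names were taken from the signal table by matching each gene's values over all regions to the probe whose counts give them, within a tolerance of 0.001 counts, which left 19936 of 19962 genes for use among 20175 probes. The 26 genes left out had no single best probe, and 3 of them combined probes. Negative probes and 29 other unnamed probes, together 0.892% of counts, stayed out of library sizes and tests. All columns of values were used. Of the genes, 19825 matched a gene of the RefSeq table for GRCm38.p6 (the mm10 assembly), from which coordinates were taken, and 111 did not. The probe positions within genes are not given in the sources used here.

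No pair of regions held identical values. Every pair within a group differed by more than sampling noise, with a lowest chi-square per degree of freedom of 1.036 and a highest p of 0.000188. Total counts per region ran from 191842 to 2169459. The headers place all regions on 1 plate and 1 run. The plate has 7 occupied rows, A to G, which were treated as a technical batch. The background share, defined below, was not uniform within rows. It was 34.1% in well B8 (FlnKO VSVZ) and 52.4% in well B9 (heterotopia). In control cortex of row F it was 66.7% in well F1 and 51.0% in well F9. Groups also run across row ends, such as FlnKO cortex from well A9 to well B2. Summing, blocking, leaving out or comparing within rows therefore does not remove differences between wells of a row. FlnKO regions lie in rows A, B, C, D and G and control regions in rows D, E and F. Only row D holds both genotypes in cortex, and no row holds both in VSVZ.

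Genes were tested with edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) on the counts with TMM scaling, using the groups compared alone. A gene was tested where it passed the limit of quantification, the negative-probe geometric mean times its geometric SD to the power 2, in at least 10% of the regions compared. P-values were adjusted by Benjamini-Hochberg, and a gene was called at an adjusted p under 0.05. The 6 tests were FlnKO against control in cortex and in VSVZ, heterotopia against FlnKO cortex and against FlnKO VSVZ, control cortex against control VSVZ, and the difference of the genotype effect between cortex and VSVZ. Log2 fold changes are given with their standard error (SE), and signals are the authors' normalised values as mean ± SD over regions. A test on background-subtracted values was run beside each count test. Here the negative-probe mean was subtracted from each count, with a floor of 1, each region was scaled to its 75th percentile, and log2 values were tested with limma-trend (limma 3.58.1). A further test took only genes with a mean count of at least 5 times the negative-probe geometric mean. It was chosen after the data were seen.

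Gene lists, 29 in all, were fixed before the data were examined, as were the groups, the count tests and the rule for named genes. The lists cover upper layer, deep layer, pan-neuronal, striatal and hippocampal neuron genes, excitatory synapse, GABAergic interneurons, GABA-A receptor subunits, ion channels, immediate early genes, neuroblasts, neural stem and progenitor cells, cell cycle, astrocytes, reactive astrocytes, oligodendrocytes and myelin, oligodendrocyte precursors, microglia, endothelial and mural cells, ependymal cells, choroid plexus, meningeal fibroblasts, blood, filamins and actin cytoskeleton, other heterotopia genes, axon guidance, oxidative phosphorylation, ribosomal proteins, and heat shock. Each list with at least 3 tested members was tested against all other genes with limma's camera at a preset correlation of 0.01, and again with an estimated correlation. Limma's fry was run as well. The named genes are Flna, Flnb, the 10 highest and 10 lowest fold changes among called genes above the median level, up to 4 called members of each list or 2 where none was called, and the 6 calls of smallest adjusted p in the difference test, also above the median level. These are 574 entries and 270 distinct genes. Names outside this rule are said to be chosen after their values were seen.

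A score placed each region on an axis between control VSVZ, set to 0, and control cortex, set to 1. It used the 100 genes with the largest fold change on each side of the control comparison. Group differences in the score were tested with 2-sided permutation tests of 100000 resamples over regions. The smallest p these can give is 2e-05.

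Each step was tested on simulated counts drawn from the real genes' means and library sizes with 200 genes changed. At a 1.5-fold change the count test recovered 98.6% for the genotype comparison in cortex and 86.2% in VSVZ. It recovered 82.5% for heterotopia against FlnKO cortex, 80% against FlnKO VSVZ, 100% for the control tissues and 77.6% for the difference test. False calls among unchanged genes numbered 14, 8, 4, 5, 5 and 12 in the same order. These simulated groups did not differ in background and shared no animals, so the false calls do not give the error rate on the real regions. With the measured backgrounds and no gene differing, the count test called a median of 4750 genes between genotypes in cortex and 2155 in VSVZ. A planted list of 20 genes was recovered in each of the 6 comparisons with no false list.

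Alternatives tried were upper quartile and total-count scaling, DESeq2 1.42.0, limma-voom, the authors' normalised signals, no filter on low genes, a filter at 50% of regions, background subtraction, all groups in one fit, plate row as a fixed or random block, counts summed within plate row, the replicate number as a block, and control regions as the reference. Alternatives added after the data were seen were a background covariate, each plate row left out in turn, summed counts with background subtraction, the control reference with background subtraction and the genes far above background. Other software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.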

Results

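Gene expression was measured in 76 regions of mouse brain sections, each read with whole-transcriptome probes after staining for neurons and astrocytes. Periventricular heterotopia is a mass of neurons that lie beside the ventricle and not in the cortex. The series asks how regional expression differs in a mouse model of this condition, in which both filamin genes Flna and Flnb, which encode actin-crosslinking proteins, are mutated. Regions came from the heterotopia (PH, 16 regions), cortex (13) and VSVZ (15) of FlnKO mice and from the cortex (16) and VSVZ (16) of control mice. Median total counts were 1650704 in control cortex, 1022151 in control VSVZ, 808138 in FlnKO cortex, 541837.5 in the heterotopia and 468331 in FlnKO VSVZ. The totals ran from 824773 to 2169459, from 428982 to 1472867, from 420419 to 1042016, from 222045 to 1471242 and from 191842 to 1104944 in the same order.

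Background differed between the genotypes. The geometric mean of the negative probes, as a percent of the region's 75th percentile gene count, was 59.2 ± 4.89% in control cortex (SD, n = 16) and 61.7 ± 3.36% in control VSVZ (n = 16). It was 34.2 ± 4.04% in FlnKO cortex (n = 13), 43.8 ± 9.62% in FlnKO VSVZ (n = 15) and 43.1 ± 9.53% in the heterotopia (n = 16). A mean of 18.8% of genes passed the limit of quantification in control cortex, 14.1% in control VSVZ, 29.1% in FlnKO cortex, 19.2% in FlnKO VSVZ and 20.6% in the heterotopia. Each genotype comparison is therefore given with counts as deposited and with background subtracted.

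**Figure D1:**
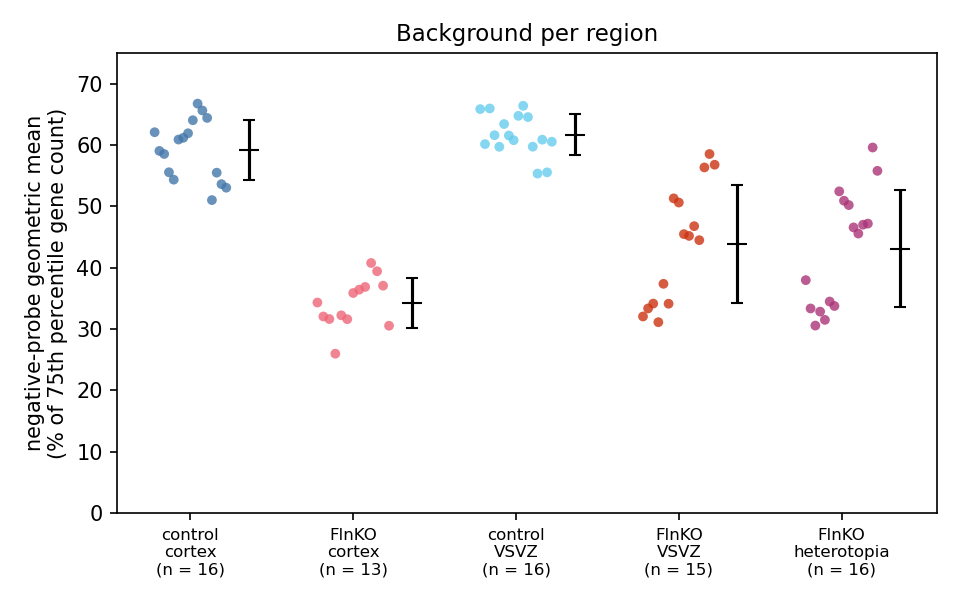
Negative-probe geometric mean as a percent of the 75th percentile gene count in each region, by group, where points are regions and the dash and bars are the mean ± SD. Control cortex averaged 59.2% and FlnKO cortex 34.2%.

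The targeted genes were low in every group. Flna (chromosome X, 74223461 to 74249854, mm10) had a signal of 10.1 ± 4.99 in FlnKO cortex, 19.6 ± 10.8 in FlnKO VSVZ and 12.3 ± 8.62 in the heterotopia, against 6.42 ± 4.24 in control cortex and 6.88 ± 4.49 in control VSVZ. It passed the limit of quantification in 0 control regions and in 3, 6 and 3 of the FlnKO cortex, VSVZ and heterotopia regions. Flnb (chromosome 14, 7817921 to 7951588) had a signal of 18.5 ± 4.21, 14.9 ± 6.46 and 19.1 ± 6.01 in the FlnKO groups and of 20.5 ± 7.99 and 17.3 ± 7.74 in control cortex and VSVZ. Flna passed no genotype test on counts, with log2 fold changes of −0.27 ± 0.12 in cortex (adjusted p = 0.0518, edgeR) and 0.24 ± 0.11 in VSVZ (adjusted p = 0.068). With background subtracted it was higher in FlnKO VSVZ by 1.80 (adjusted p = 0.000643, limma-trend). Flnb fell by 0.28 in cortex (adjusted p = 0.00914, edgeR) and fell by 0.37 in VSVZ (adjusted p = 0.0014). With background subtracted its adjusted p was 0.788 and 0.597. Which part of each gene the probes cover is not given in the sources used here, so these values check nothing about the genotype.

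In FlnKO cortex, genes of neurons and their synapses were higher than in control cortex. Mef2c, a transcription factor of excitatory neurons (chromosome 13, 83504017 to 83667079), rose by 1.37 ± 0.14 on the log2 scale, from a signal of 153 ± 58.6 (n = 16) to 329.7 ± 39.6 (n = 13), with an adjusted p of 2.3e-10. Ppp3ca, a subunit of calcineurin, rose by 1.28 ± 0.17 and Stxbp1, which acts in vesicle release, by 1.24 ± 0.14. Ndufs2, a subunit of mitochondrial complex I, rose by 0.92 ± 0.11, from 42.0 ± 20.5 to 83.5 ± 13.9. These 4 also rose over 2-fold with background subtracted, among 16 genes far above background that did so. The other 12 were named after their values were seen and include Ndn, an imprinted neuronal gene, which rose by 1.21 ± 0.19, and the RNA-binding protein gene Fus, which rose by 1.00 ± 0.11. Of the 5 such genes that fell over 2-fold, Hikeshi, a nuclear importer of Hsp70, had a background-subtracted log2 fold change of −1.63 ± 0.13 and the retinoic acid receptor gene Rara one of −1.05 ± 0.12, both also chosen after their values were seen. Another of the 5, Erdr1, was not called on counts, where its log2 fold change was 0.42 (adjusted p = 0.41, edgeR).

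By gene list, 13 of 15 pan-neuronal genes tested rose in FlnKO cortex (median log2 fold change 0.72), as did 17 of 20 excitatory synapse genes (0.61) and 16 of 17 ion channel genes (0.52), with none falling. Slc17a7, the vesicular glutamate transporter, rose by 1.12 ± 0.14 and Scn8a, a sodium channel gene, by 0.83 ± 0.08. Among mitochondrial genes of oxidative phosphorylation 19 of 28 rose (0.39), and 24 of 30 ribosomal protein genes rose while 1 fell (0.26). All 6 other heterotopia genes tested rose (0.50), among them Map1b, a microtubule protein gene, by 0.70 ± 0.10. In the filamin and actin list 10 of 17 rose and 2 fell (0.25), led by the actin gene Actg1 at 0.81 ± 0.10. In regions simulated with the measured backgrounds and no gene differing, genes above the 75th percentile of level had a median log2 fold change of 0.38 to 0.40, which the oxidative phosphorylation, ribosomal and actin medians did not clearly exceed. With background subtracted the order changed. Medians were then 0.468 for pan-neuronal, 0.336 for synapse, 0.428 for ion channel and 0.485 for oxidative phosphorylation genes. They were 0.406 for actin and 0.041 for ribosomal genes, against 0.286 for all genes. Microglial genes went the other way, with 6 of 8 falling (−0.50). Aif1, a microglial calcium-binding protein gene, fell by 1.05, from a signal of 26.8 ± 4.83 to 8.69 ± 5.94, and the complement gene C1qb fell by 0.79. These 8 lists passed the camera test, with adjusted p from 3.52e-06 for the pan-neuronal and synapse lists to 0.0277 for the actin and microglial lists. With an estimated correlation none did, and adjusted p ran from 0.211 to 0.298. With background subtracted 3 passed, pan-neuronal (adjusted p = 0.0385), ion channels (0.0318) and oxidative phosphorylation (0.0318). The ribosomal list turned to lower only relative to the other genes (camera adjusted p = 0.79), with 8 of its genes called higher and 4 lower. With an estimated correlation as well, 0 lists passed, and each of those 3 had a camera adjusted p of 0.701.

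The other 15 lists tested in this comparison did not pass. Upper layer genes gave 8 higher and 2 lower of 16, deep layer 1 and 3 of 6, interneurons 6 and 2 of 13, striatal 2 and 3 of 7, hippocampal 0 and 2 of 3, neuroblasts 4 and 3 of 10, and stem and progenitor genes 0 and 1 of 4. Astrocyte genes gave 6 higher and 3 lower of 14, myelin 1 and 4 of 11, oligodendrocyte precursors 0 and 3 of 5, endothelial and mural 1 and 3 of 7, GABA-A receptor subunits 5 and 2 of 9, immediate early genes 2 and 0 of 10, axon guidance 4 and 5 of 17, and heat shock 4 and 2 of 9. The striatal and endothelial lists had medians of 0.13 and 0.08 and means of −0.10 and −0.21. Adjusted over the list alone, the counts of 18 lists were the same. Those of pan-neuronal genes became 14 higher, oxidative phosphorylation 20 higher and 1 lower, actin 3 lower, myelin 2 lower and axon guidance 4 lower.

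In all, 4768 of 7854 genes were called in cortex by edgeR, 2346 higher and 2422 lower, and 2859 passed in the same direction with background subtracted (1819 higher and 1040 lower, while 49 passed in opposite directions). Upper quartile scaling gave 1300 higher and 3965 lower, total-count scaling 1213 and 4093, the authors' signals 3066 and 1131, and background subtraction 3001 and 1122, with the median of all genes at −0.21, −0.23, 0.25 and 0.29. Changes given here are relative to a median of −0.02 under TMM scaling. In regions simulated with the measured backgrounds and no gene differing, the count test alone called a median of 4750 genes, 99.62% of the observed 4768. Both tests together called a median of 2173 genes there. Only plate row D holds cortex of both genotypes. There 98.4% of the genes called higher and 70.5% of those called lower had the same sign, with Mef2c at 1.79, Ppp3ca at 2.24 and Stxbp1 at 1.18. The row D regions also entered the calls, so part of this agreement is built in. Their background share averaged 37.0% in FlnKO cortex and 59.9% in control cortex, so row D does not separate genotype from background. Some regions share an animal, so the p-values are too small. The background share ran from 26.0 to 40.8% in FlnKO cortex and from 51.0 to 66.7% in control cortex, so as a covariate, which left 1 call of 4768, it can hardly be separated from genotype. Counts summed within plate row left 3575 calls and, with background subtracted as well, 2587.

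Neuronal genes were also higher in FlnKO VSVZ than in control VSVZ. Slc17a7 rose by 1.71 ± 0.28, from a signal of 68.9 ± 73.0 (n = 16) to 239.8 ± 131 (n = 15), with an adjusted p of 9.9e-06. Snap25, which acts in vesicle fusion, rose by 1.56 ± 0.28 and Stxbp1 by 1.47 ± 0.20. The astrocytic glutamate transporter Slc1a2 rose by 1.27 ± 0.19, from 251 ± 109 to 522 ± 141, and Actg1 by 1.17 ± 0.14. Ccn2, a deep layer marker of the list used, rose by 1.10 ± 0.27, and Serpina3n, a marker of reactive astrocytes, by 0.79 ± 0.15. Hikeshi fell by 1.09, from 218 ± 244 to 76.8 ± 28.6. Among genes far above background 116 changed over 2-fold with background subtracted, 113 of them higher, and the same test on simulated regions with no gene differing gave 0. The simulation gave all genes a common dispersion and took regions as independent, so that 0 does not show what unequal regions would give. Of the 3 lower genes, Penk and Erdr1 were not called on counts, with log2 fold changes of 0.05 and 0.08.

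All 14 pan-neuronal genes tested rose in FlnKO VSVZ (median 0.96), with 15 of 18 synapse genes (0.72), 10 of 16 ion channel genes (0.38) and 3 of 5 other heterotopia genes (0.53). The ion channel gene Scn1b rose by 1.21 ± 0.20. Oxidative phosphorylation genes rose in 17 of 26 cases and fell in 1 (0.42), and Atp5b, a subunit of ATP synthase, rose by 1.16 ± 0.16. Of the astrocyte genes 6 of 12 rose (0.37), of the myelin genes 8 of 17 (0.33), of the actin list 8 of 17 with 1 falling (0.24) and of the ribosomal genes 12 of 30 (0.22). Plp1, the main protein of central myelin, rose by 0.74 ± 0.22. Genes above the 75th percentile of level had a median of 0.24 to 0.26 in simulated regions with no gene differing, at or above the actin and ribosomal medians. Microglial genes fell in 6 of 9 cases (−0.38), with Ctss at −0.57 ± 0.14 and C1qb at −0.54 ± 0.11. Camera passed these 10 lists, from an adjusted p of 4.23e-08 for pan-neuronal genes to 0.0204 for myelin. No list passed with an estimated correlation, where adjusted p ran from 0.344 to 0.653. With background subtracted the myelin list did not pass (adjusted p = 0.876) and the ribosomal list turned to lower relative to the other genes (0.876). With an estimated correlation as well, 0 lists passed.

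No other list passed in VSVZ on counts. Upper layer genes gave 1 higher and 2 lower of 7, deep layer 8 and 1 of 11, interneurons 4 and 3 of 10, striatal 0 and 2 of 13, hippocampal 0 and 2 of 3, neuroblasts 3 and 2 of 9, stem and progenitor genes 1 and 1 of 5, and cell cycle 0 and 2 of 3. Reactive astrocyte genes gave 1 higher and 1 lower of 3, oligodendrocyte precursors 2 and 2 of 10, endothelial and mural 2 and 3 of 7, GABA-A receptor subunits 2 and 1 of 5, immediate early genes 2 and 0 of 8, axon guidance 3 and 3 of 11, and heat shock 2 and 1 of 8. The striatal list had an adjusted p of 0.0982 on counts and passed as lower with background subtracted (0.0146), but not with an estimated correlation as well (0.660). Adjusted over the list alone, ion channel genes gave 11 higher, ribosomal genes 9 higher, microglial genes 7 lower, striatal genes 1 lower, endothelial genes 4 lower and axon guidance 4 higher, and the counts of the others were the same.

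The VSVZ comparison called 2883 of 6106 genes, 1411 higher and 1472 lower, of which 1216 and 812 passed in the same direction with background subtracted and 0 in the opposite direction. Upper quartile scaling gave 835 higher and 2216 lower, total-count scaling 773 and 2384, the authors' signals 1852 and 866, and background subtraction 1830 and 838, with the median of all genes moving from 0.00 to −0.13, −0.15, 0.26 and 0.30. In simulated regions with no gene differing, the count test alone called a median of 2155 genes, 74.75% of the observed 2883. Both tests together called a median of 683 genes there, against 2028 observed. Some regions share an animal, which makes these p-values too small. No plate row holds VSVZ of both genotypes, so row and genotype cannot be told apart. Counts summed within plate row left 1 call of 2883 by edgeR (2091 at an unadjusted p under 0.05), plate row as a random block 1885 and the background share as a covariate 8.

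Cwc22, which encodes a splicing factor (chromosome 2, 77881159 to 77946356), had the lowest fold change of the named genes in both tissues. It fell by 2.24 in cortex, from 134 ± 83.9 to 14.7 ± 4.51 (adjusted p = 1.13e-08), and fell by 1.77 in VSVZ, from 114 ± 78.2 to 18.6 ± 9.01 (adjusted p = 6.12e-07). With background subtracted it fell by 2.89 and fell by 2.52, respectively. In plate row D the difference in cortex was −2.56. Control values split both between and within plate rows. In control cortex they ran from 175 to 238 in row D and from 138 to 251 in row E, and in row F 3 regions lay between 116 and 131 and 4 between 11.9 and 21.5. In control VSVZ they ran from 185 to 227 in row D, from 88.9 to 132 in row E and from 16.3 to 30.5 in row F. All FlnKO regions lay between 4.84 and 35.3, and 4 cortical and 5 VSVZ control regions were at or below 35.3.

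**Figure D2:**
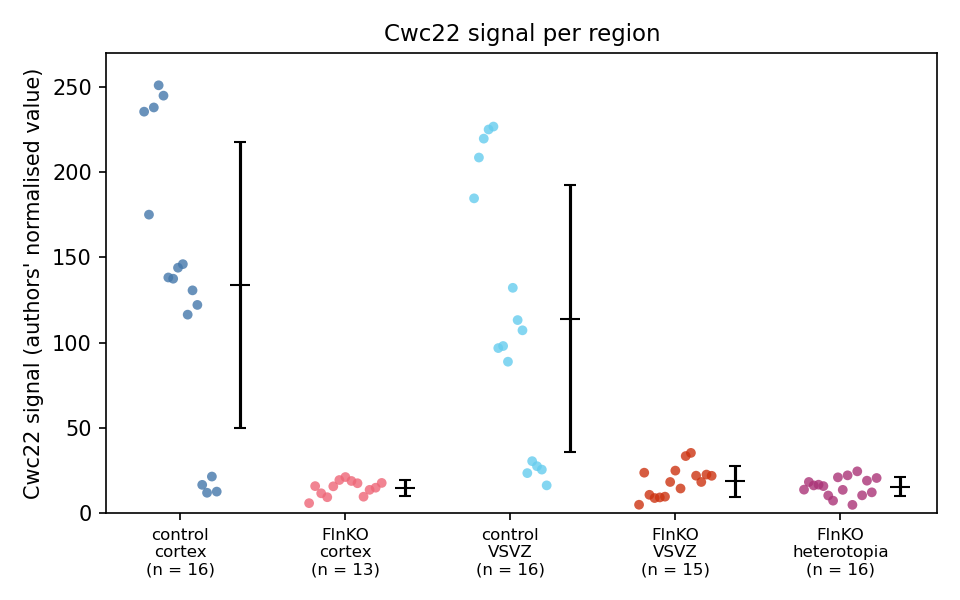
Normalised signal of Cwc22 in each region, by group, where points are regions and the dash and bars are the mean ± SD. FlnKO regions lie between 4.84 and 35.3 and control regions between 11.9 and 251, with 9 of the 32 control regions at or below 35.3.

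The heterotopia was compared with FlnKO cortex to find what sets the misplaced tissue apart from cortex of the same genotype. Transthyretin (Ttr, chromosome 18, 20664209 to 20674326), a product of the choroid plexus, rose by 4.35 ± 0.52, from a signal of 6.76 ± 4.51 (n = 13) to 331 ± 425 (n = 16), with an adjusted p of 5.91e-06. All 16 heterotopia regions were above the highest FlnKO cortex region. Genes of striatal projection neurons were higher as well. Ppp1r1b (chromosome 11, 98348406 to 98357796), which encodes DARPP-32, rose by 3.14 ± 0.55, from 58.4 ± 26.2 to 684 ± 818, and the enkephalin gene Penk by 3.35 ± 0.62, from 31.2 ± 14.3 to 469 ± 606. Their SD in the heterotopia exceeded their mean. Most myelin genes tested also rose, and 10 of 15 pan-neuronal genes, such as Snap25, fell. The fall of Snap25 was uneven, at −0.18, −1.79 and −1.47 in plate rows A, B and C.

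Of the 14 striatal genes tested 13 rose (median 2.13), including the dopamine receptor gene Drd2 by 2.63 ± 0.46. Myelin genes rose in 13 of 14 cases (1.07), with Mobp at 1.66 ± 0.33 and Plp1 at 1.53 ± 0.32, and oligodendrocyte precursor genes in 4 of 5 (0.81), with Sox10 at 1.18 ± 0.18. Of the choroid plexus genes 2 of 3 rose (1.06), Ttr and Kl, the latter by 1.06 ± 0.18. Microglial genes rose in 6 of 8 cases (0.43), astrocyte genes in 4 of 14 (0.22) and ependymal genes in 1 of 3 (0.44). With background subtracted 0 of the 8 microglial genes were called, though the list passed camera (adjusted p = 0.0145). Downward, 10 of 15 pan-neuronal genes (−0.53), 7 of 20 synapse genes (−0.39), 10 of 17 ion channel genes (−0.37), 11 of 28 oxidative phosphorylation genes (−0.22) and 3 of 7 other heterotopia genes (−0.22) fell. Snap25 fell by 0.89, from 1556 ± 366 to 861 ± 416, and Scn1b fell by 1.05. In plate rows A, B and C Vsnl1 differed by −0.03, −1.64 and −1.36 and Syn1 by −0.27, −1.65 and −0.80. Nefm differed by 0.10, −0.06 and −1.81, Nrgn by −0.18, −1.08 and −1.04, and Scn1b by −0.26, −1.63 and −1.78. Heterotopia regions of row A had at most 5 of 14 striatal genes above every FlnKO cortex region. Whether striatal content lowers these genes was not tested. With control cortex as the reference in place of FlnKO cortex, the mitochondrial genes Ndufs2, Atp5o, Atp5b and Atp5a1 turned to higher (0.47, 0.28, 0.56 and 0.55), and the microglial gene Aif1 turned to lower (−0.40), all past the threshold. These 12 lists passed camera, with adjusted p from 2.1e-10 for myelin to 0.0486 for the ependymal and other heterotopia lists. None passed with an estimated correlation, where adjusted p ran from 0.104 to 0.219. With background subtracted and an estimated correlation, the myelin (adjusted p = 0.0374), precursor (0.0119) and choroid plexus (0.0137) lists passed. The other heterotopia list did not pass with background subtracted (adjusted p = 0.157).

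**Figure D3:**
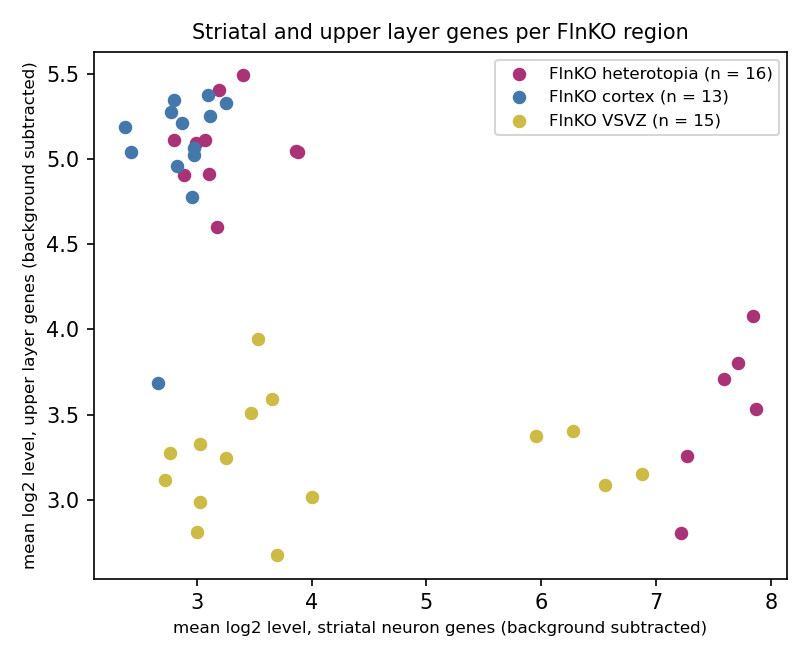
Mean background-subtracted log2 level of the striatal list against that of the upper layer list in each FlnKO region, where each point is 1 region and its marker gives the group. The striatal mean runs from 2.80 to 7.87 in the heterotopia, from 2.38 to 3.26 in cortex and from 2.72 to 6.88 in VSVZ.

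Lists that did not pass against FlnKO cortex were upper layer genes, with 2 higher and 3 lower of 16 (median −0.47), deep layer with 5 and 1 of 9 (0.82), interneurons with 2 and 0 of 13, hippocampal with 2 and 0 of 4, neuroblasts with 3 and 2 of 12, stem and progenitor genes with 2 and 0 of 4, endothelial and mural with 0 and 0 of 6, and actin with 0 and 1 of 17. GABA-A receptor subunits gave 0 and 3 of 9, immediate early genes 0 and 0 of 11, axon guidance 4 and 4 of 18, ribosomal genes 0 and 1 of 30, and heat shock 0 and 1 of 9. The upper layer genes Lamp5 and Satb2 had log2 fold changes of −1.03 ± 0.24 and −0.75 ± 0.21. They differed by −0.12, −1.19 and −1.61 and by −0.31, −1.93 and −1.08 in plate rows A, B and C. In the 6 heterotopia regions with all 14 striatal genes above every FlnKO cortex region, the mean upper layer level (log2, background subtracted) ran from 2.81 to 4.08. In the other heterotopia regions it ran from 4.60 to 5.49, and in FlnKO cortex from 3.68 to 5.38. The deep layer genes Pcp4 and Syt6 rose by 2.51 ± 0.54 and 1.74. Their differences in rows A, B and C were 0.33, 1.90 and 1.70 and 0.46, 2.53 and 1.09, lowest in row A as those of Ppp1r1b and Penk were, and Syt6 passed the limit of quantification in 6 of 16 heterotopia regions. With background subtracted the deep layer list passed as higher (adjusted p = 0.00792), as did the ribosomal list (0.00585). Neither passed with an estimated correlation as well (camera adjusted p = 0.0925 and 0.430). Adjusted over the list alone, myelin gave 14 higher, microglia 7, choroid plexus 3, deep layer 6, hippocampal 3 with 1 lower and ependymal 2. Pan-neuronal genes gave 13 lower, ion channels 11, oxidative phosphorylation 12, upper layer 6, GABA-A receptor subunits 4, axon guidance 5 with 5 higher, and actin and ribosomal genes 0.

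This comparison called 1681 of 7980 genes, 883 higher and 798 lower, and 132 and 462 of them passed in the same direction with background subtracted. Higher against lower calls were 1399 and 561 with upper quartile scaling, 1669 and 448 with total-count scaling, 137 and 719 with the authors' signals and 134 and 534 with background subtracted, and the median of all genes moved from 0.02 to 0.10, 0.12, −0.17 and −0.19. Within rows A, B and C, which hold both groups, 62.2% of the higher and 88.5% of the lower calls had the same sign in each row. Those regions also entered the calls. The background share in these rows averaged 33.5, 50.0 and 46.6% in the heterotopia and 31.0, 31.9 and 36.4% in FlnKO cortex. Differences in rows B and C therefore span a background gap. Ttr differed by 4.92, 2.57 and 3.32 in rows A, B and C, Ppp1r1b by 0.70, 4.28 and 1.14, Penk by 0.19, 3.93 and 1.96, Plp1 by 1.30, 2.21 and 0.95, and Snap25 by −0.18, −1.79 and −1.47. Some regions share an animal, so these p-values too are smaller than animals would give. Counts summed within plate row left 1 call by edgeR (1883 at an unadjusted p under 0.05), plate row as a fixed block 808 and the background share as a covariate 24. Without row A there were 2844 calls, without row B 482, without row C 823, without row D 921 and without row G 777.

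Against FlnKO VSVZ, 9 of 12 upper layer and 15 of 19 synapse genes tested were called higher in the heterotopia, and 7 of 13 deep layer and all 17 myelin genes lower. On counts none of these lists passed camera with an estimated correlation. Camk2a, a kinase of excitatory synapses, rose by 1.92 ± 0.28, from a signal of 243 ± 146 (n = 15) to 978 ± 449 (n = 16), and Cux2, an upper layer transcription factor, by 1.66 ± 0.30, from 12.4 ± 9.75 to 75.05 ± 58.0. The activity-dependent gene Egr3 rose by 1.48 ± 0.18 (adjusted p = 4.31e-08). Plp1 fell by 2.74, from 1395 ± 507 to 229 ± 190 (adjusted p = 3e-09), and the deep layer genes Ccn2 (chromosome 10, 24595442 to 24598683) and Cplx3 had log2 fold changes of −2.59 ± 0.25 and −2.35 ± 0.27. Ttr rose by 2.89 ± 0.46.

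Of the upper layer genes 9 of 12 rose (median 0.80), with 15 of 19 synapse genes (0.89), 8 of 15 pan-neuronal genes (0.58) and 6 of 12 interneuron genes (0.59), such as Gad1, which makes GABA, by 1.04 ± 0.19. Ion channel genes rose in 14 of 17 cases and fell in 2 (0.65), GABA-A receptor subunits rose in 5 of 8 (0.57), immediate early genes rose in 6 and fell in 1 of 9 (0.42), and oxidative phosphorylation genes rose in 5 of 28 (0.20). All 17 myelin genes fell (−1.94), with 5 of 8 precursor genes (−0.77), 7 of 13 deep layer genes (−0.68), 3 of 5 stem and progenitor genes (−0.52) and 16 of 30 ribosomal genes (−0.25). Sox10, which sets oligodendrocyte fate, fell by 1.90, and Thbs4, of the stem and progenitor list, fell by 1.07. These 13 lists passed camera, from an adjusted p of 2.65e-27 for myelin to 0.0257 for interneurons. With an estimated correlation none passed, and adjusted p ran from 0.0611 for myelin to 0.260. With background subtracted as well, the myelin (adjusted p = 0.0272), deep layer (0.0322) and precursor (0.0322) lists passed. Interneuron genes did not pass with background subtracted (adjusted p = 0.079).

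Striatal genes gave 1 higher and 0 lower of 14 here (median 0.80, adjusted p = 0.22). Hippocampal genes gave 0 and 1 of 3, neuroblasts 3 and 2 of 10, cell cycle 0 and 1 of 3, astrocytes 1 and 2 of 13, microglia 0 and 1 of 8, endothelial and mural 0 and 1 of 6, actin 2 and 3 of 17, other heterotopia genes 1 and 1 of 6, axon guidance 7 and 5 of 18, and heat shock 1 and 0 of 9, none of which passed on counts. With background subtracted the hippocampal list passed as lower (adjusted p = 0.0399), but not with an estimated correlation as well (0.193). The guidance genes Slit3 and Efnb3 rose by 1.24 and fell by 1.83, respectively. Adjusted over the list alone, pan-neuronal genes gave 10 higher, upper layer 10, synapse 16, interneurons 7 and GABA-A receptor subunits 6, while deep layer genes gave 8 lower, stem and progenitor genes 4, ribosomal genes 17, neuroblasts 3 and endothelial genes 0.

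In this comparison 1675 of 6599 genes were called, 923 higher and 752 lower, and 881 and 583 passed in the same direction with background subtracted. Background subtraction alone gave 1261 higher and 587 lower and the authors' signals 1290 and 596, with the median of all genes at 0.15 and 0.13 against −0.00 under TMM. Rows B, C and G hold both groups. The sign was the same in each of them for 74.8% of the higher and 84.6% of the lower calls. Those regions also entered the calls. The background share in rows B, C and G averaged 50.0, 46.6 and 57.7% in the heterotopia and 33.7, 47.3 and 57.2% in FlnKO VSVZ. Differences in row B therefore span a background gap. Camk2a differed by 0.72, 2.08 and 0.75 in rows B, C and G, Plp1 by −3.19, −2.62 and −0.96, Cux2 by 0.42, 1.78 and −0.22, and Ttr by 0.70, 3.14 and −0.35. As above, regions that share an animal make the p-values too small. Counts summed within plate row left 336 calls, and without row C there were 1105.

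**Figure D4:**
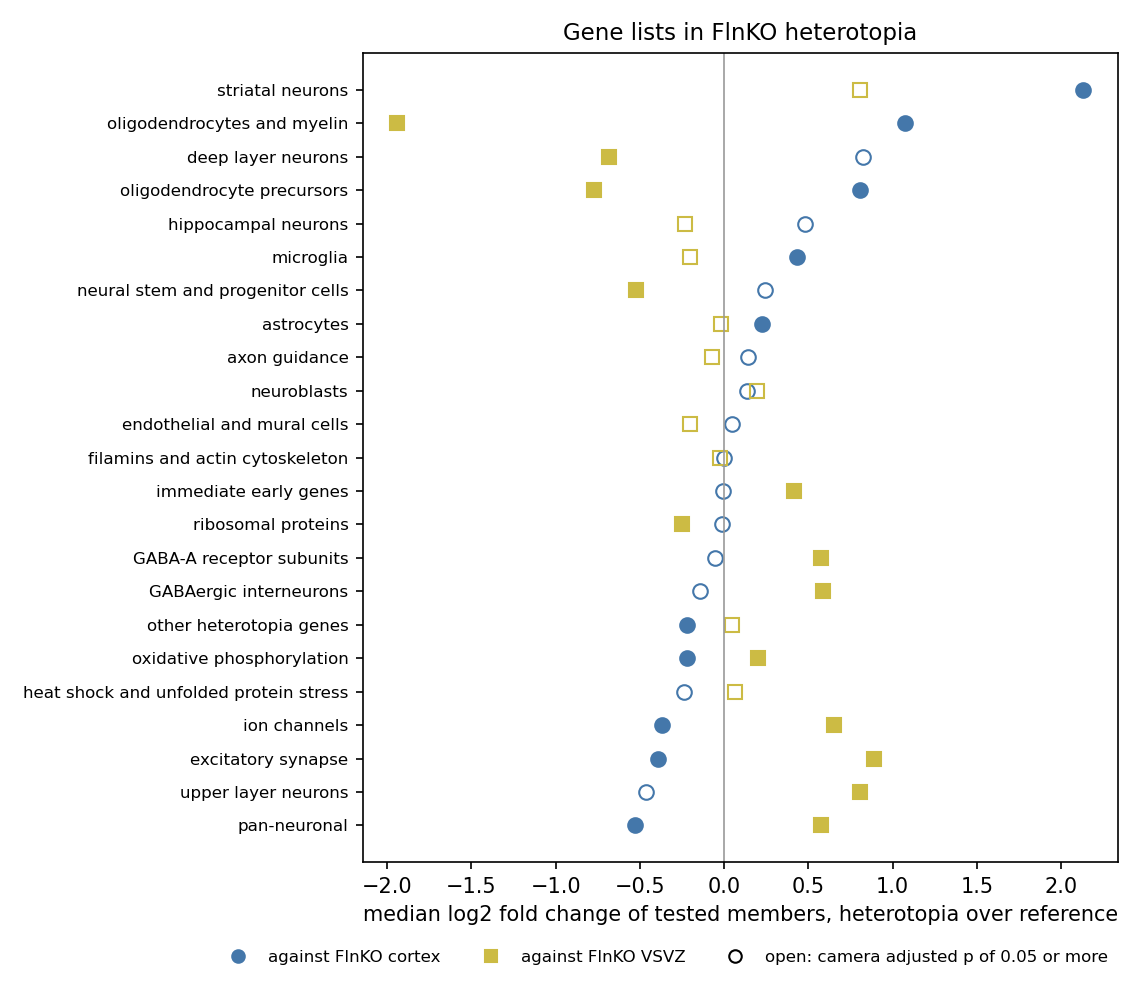
Median log2 fold change of each gene list in the heterotopia against FlnKO cortex (circles) and against FlnKO VSVZ (squares), with filled markers where camera gave an adjusted p under 0.05. Striatal genes reach 2.13 against cortex and myelin genes −1.94 against VSVZ.

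Control cortex and control VSVZ gave the reference for these tissue differences. Camk2a was higher in cortex by 2.67 ± 0.22, from a signal of 99.4 ± 75.9 to 833 ± 217 (n = 16 each), and the postsynaptic gene Nrgn by 2.72 ± 0.29. Cux2 was higher by 1.81 ± 0.15. Mobp was lower in cortex by −3.93 ± 0.18, at 54.7 ± 25.6 against 1119 ± 318, and Plp1 by −3.85 ± 0.24. Ppp1r1b and Ccn2 were lower by −1.72 ± 0.25 and −1.68. Flna was below the filter, and Flnb had a log2 fold change of −0.07 ± 0.08 (adjusted p = 0.481).

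All 15 pan-neuronal genes were higher in control cortex (median 1.40), with 19 of 20 synapse genes (1.08), 9 of 13 upper layer genes (0.66), 14 of 17 ion channel genes with 2 lower (0.70), 5 of 6 GABA-A receptor subunits (0.60) and 21 of 24 oxidative phosphorylation genes (0.42). Lower in cortex were 17 of 17 myelin genes (−2.26), 6 of 6 precursor genes (−0.84), 11 of 12 striatal genes with 1 higher (−0.97), 7 of 9 deep layer genes with 1 higher (−0.66), 3 of 3 hippocampal genes (−0.60), 4 of 5 stem and progenitor genes (−0.59), 8 of 9 microglial genes (−0.49) and 19 of 30 ribosomal genes (−0.24). These 14 lists passed camera, from an adjusted p of 2.21e-17 for myelin to 0.0421 for hippocampal genes. With an estimated correlation none passed, with adjusted p from 0.158 to 0.295. With background subtracted as well, myelin (adjusted p = 0.00407) and precursor genes (0.0206) passed. Interneurons gave 7 higher and 2 lower of 13, neuroblasts 2 and 4 of 8, astrocytes 2 and 3 of 11, reactive astrocytes 0 and 1 of 3, endothelial and mural 1 and 3 of 6, actin 6 and 3 of 13, other heterotopia genes 4 and 0 of 6, immediate early genes 5 and 2 of 8, axon guidance 5 and 4 of 11, and heat shock 5 and 0 of 9, and did not pass on counts. With background subtracted the heat shock list passed as higher (adjusted p = 0.046), but with an estimated correlation as well no list passed as higher. Adjusted over the list alone, neuroblasts gave 3 higher and 5 lower and reactive astrocytes 3 lower, and the other counts were the same.

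Control tissues differed in 3700 of 5774 genes, 1763 higher in cortex and 1937 lower, of which 1763 and 778 passed in the same direction with background subtracted. Upper quartile scaling gave 1441 higher and 2433 lower, total-count scaling 1403 and 2492, the authors' signals 2539 and 791, and background subtraction 2524 and 778, with the median of all genes at −0.12, −0.13, 0.26 and 0.31 against −0.04. In each of rows D, E and F, whose regions also entered the calls, 99.7% of the higher and 50.7% of the lower calls had the same sign. Camk2a differed by 2.02, 3.54 and 3.18 and Mobp by −3.24, −3.30 and −4.51 in these rows. Regions share animals here too, and the p-values are too small. Counts summed within plate row left 2405 calls.

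The genotype effect itself differed between cortex and VSVZ in 575 of 7575 genes, 242 with a more positive effect in cortex and 333 with a more negative one, of which 3 and 45 passed in the same direction with background subtracted. Deep layer genes were more negative in cortex in 7 of 14 cases (median −0.98), myelin genes in 8 of 17 (−0.79) and precursor genes in 5 of 9 (−0.44). Upper layer genes were more positive in 4 of 13 cases (0.54), with Calb1, a calcium-binding protein gene, at 0.94. These lists passed camera, and the upper layer (adjusted p = 0.0390), deep layer (0.0350) and precursor (0.0350) lists also passed with an estimated correlation, where myelin had an adjusted p of 0.0558. With background subtracted the upper layer (adjusted p = 0.388), deep layer (0.354), myelin (0.797) and precursor (0.831) lists did not pass, and the pan-neuronal (2.34e-07), synapse (2.53e-08) and oxidative phosphorylation (0.000299) lists passed as more negative. With an estimated correlation as well, the pan-neuronal, synapse and oxidative phosphorylation lists did not pass (camera adjusted p = 0.697, 0.697 and 0.771). Hippocampal (adjusted p = 0.0273), astrocyte (0.0385), reactive astrocyte (0.0437) and pan-neuronal (0.0471) lists passed as more negative on counts and not with an estimated correlation (0.119, 0.493, 0.0711 and 0.647). None of the 15 pan-neuronal genes was called (edgeR), and 1 of 3 hippocampal, 1 of 14 astrocyte and 2 of 3 reactive astrocyte genes were.

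Among the other lists of the difference test, interneurons, striatal neurons, cell cycle, synapse and ribosomal genes held no call of 13, 13, 3, 20 and 30 genes. Neuroblasts gave 1 more positive of 10, stem and progenitor genes 1 more negative of 5, microglia 1 more negative of 9, endothelial and mural 1 of 7, actin 1 of 17, immediate early genes 1 of 10 and oxidative phosphorylation 1 of 28. Ion channel genes gave 4 more positive of 17, GABA-A receptor subunits 2 of 9, other heterotopia genes 1 of 6, heat shock 1 of 9, and axon guidance 4 with 3 more negative of 19. Adjusted over the list alone, upper layer genes gave 6, deep layer 8, myelin 11, hippocampal 2, striatal 3 more negative, GABA-A receptor subunits 3, axon guidance 6 and 5, and oxidative phosphorylation 0. Meningeal fibroblast and blood genes had under 3 tested members in every comparison, and ependymal and choroid plexus genes in all but heterotopia against FlnKO cortex. With background subtracted the difference test called 11 more positive and 151 more negative genes, with the authors' signals 6 and 73, with upper quartile scaling 106 and 715 and with total-count scaling 123 and 534, and the median of all genes moved from 0.00 to −0.16, −0.12, −0.12 and −0.09. Some regions share an animal, and counts summed within plate row left 29 calls, plate row as a fixed block 251.

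On an axis from control VSVZ, with a mean score of 0 ± 0.221 (SD, n = 16), to control cortex, at 1 ± 0.0939 (n = 16), the heterotopia lay between the FlnKO tissues. Its mean score was 0.9225 ± 0.339 (n = 16), against 1.285 ± 0.0528 in FlnKO cortex (n = 13) and 0.2475 ± 0.194 in FlnKO VSVZ (n = 15). It differed from FlnKO cortex by −0.362 and from FlnKO VSVZ by 0.675, each with a permutation p of 2e-05, the smallest the test can give, and 2.7e-05 adjusted over 4 tests. Of the 16 heterotopia regions 13 scored below every FlnKO cortex region and 13 above every FlnKO VSVZ region. FlnKO cortex scored above control cortex by 0.285 (permutation p = 2e-05), but with background subtracted the difference was −0.0263 (p = 0.0510). FlnKO VSVZ scored above control VSVZ by 0.2475 (p = 0.00336), but no plate row holds both. Heterotopia scores averaged 1.191 in plate row A, 0.705 in row B, 0.946 in row C and 0.381 in row G, while the mean striatal level, whose genes were mostly lower in control cortex than in control VSVZ, ran the other way at 3.22, 6.77, 4.61 and 7.25 in these rows. Row G holds only heterotopia regions 15 and 16, whose titles name no tissue. Their mean upper layer levels (log2, background subtracted) were 2.81 and 3.25, within the FlnKO VSVZ range of 2.68 to 3.95. FlnKO cortex averaged 1.314, 1.292, 1.252 and 1.277 in rows A, B, C and D, and FlnKO VSVZ 0.236, 0.299 and 0.167 in rows B, C and G. In rows D, E and F control VSVZ averaged 0.179, −0.0395 and −0.132, so its row D lay above row G of FlnKO VSVZ, and control cortex averaged 0.972, 0.971 and 1.037. Regions that share an animal make these p-values too small.

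**Figure D5:**
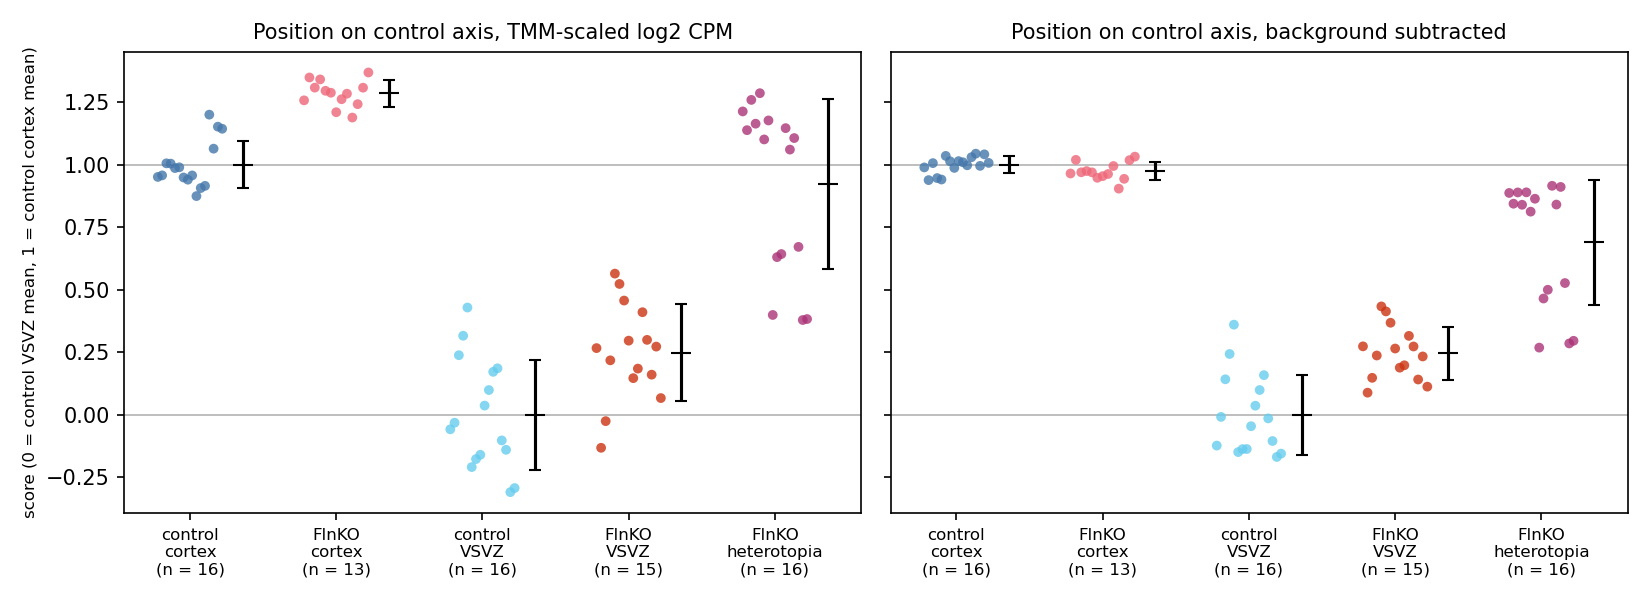
Score of each region on the axis from control VSVZ (0) to control cortex (1), on counts with TMM scaling and with background subtracted, where points are regions and the dash and bars are the mean ± SD. Heterotopia regions run from 0.379 to 1.286 with TMM scaling and from 0.269 to 0.916 with background subtracted.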

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

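Tests chosen only after the result was seen are those of few independent animals or plate rows, of striatal tissue inside the heterotopia regions, and of genotype and strain for Cwc22.

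The results of this paragraph stood out because the genotype effect in cortex differed from that in VSVZ by a test of the difference itself, whereas the 3 patterns after it were taken up for their size. The difference test called 575 genes, and the values here are log2 fold changes in cortex minus those in VSVZ. Among called genes with a level above the median, those of the smallest adjusted p were Jup (−0.87), Igsf21 (−1.11), Nxph3 (−1.69), Gjc2 (−1.33), Padi2 (−0.95) and Pdlim2 (−0.97). The 4 of 13 upper layer genes called were Calb1 (0.94), Rasgrf2 (0.80), Stard8 (0.70) and Pou3f2 (0.54), and the list had a median of 0.54. Of the deep layer genes 7 of 14 were called, among them Rprm (−1.61), Cplx3 (−1.44), Ccn2 (−1.43) and Nxph4 (−1.27), with a list median of −0.98. In cortex these 4, and Opalin, passed the limit of quantification in at most 1 of 13 FlnKO and in 0 of 16 control regions, and Nxph3, Gjc2, Padi2, Pdlim2, Ugt8a, Gpr17, Enpp6, C4b, Thbs4 and Sema5a in 0 of either, so the cortical values behind these differences lie near background. The myelin list had a median of −0.79, with Ugt8a at −1.20, Opalin at −1.07, Trf at −0.95 and Gjc2 at −1.33. The precursor list had a median of −0.44, with Gpr17 at −0.93, Sox10 at −0.75, Enpp6 at −0.68 and Bcas1 at −0.57. Astrocyte genes had a median of −0.0779 and reactive astrocyte genes one of −0.54, with Gfap (a stain used to choose regions) at −1.21, C4b at −0.88 and Steap4 at −0.54. The pan-neuronal list had a median of −0.25 and the hippocampal list one of −0.46, with Prox1 at −0.56. The 4 ion channel genes called were Kcnh1 (0.72), Kcnd2 (0.67), Cacna1c (0.43) and Scn1a (0.38), and the 2 GABA-A receptor subunits Gabra4 (0.51) and Gabrd (0.46), but neither list passed camera. Of the guidance genes Efna5 (0.68) and Epha4 (0.66) were more positive and Sema5a (−0.90) and Efnb3 (−0.82) more negative. Single genes of other lists were Thbs4 (stem and progenitor cells) at −0.82, Nrep at 0.80, Aif1 at −0.60, Tek at −0.49, Ttr at −0.97, Flna at −0.51, Nedd4l at 0.36, Arc at −0.53, Ndufb9 at −0.36 and Dnajb1 at 0.40. With background subtracted 162 genes were called, 11 of them more positive, and of the genes named in this paragraph only Jup, Igsf21, Trf, Aif1, Arc and Ndufb9 were among them, while Pou3f2, Gabra4, Nedd4l and Dnajb1 changed sign. Of 100 splits of the same regions, which moved genotype labels within each tissue, the real one gave the most calls (575, highest other 1). Such splits remove the genotype effect in each tissue along with its difference between tissues. They therefore cannot exclude chance for the difference itself, and regions of 1 animal are not independent samples.

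Many genes were called between genotypes. In cortex, regions simulated with the measured backgrounds and no gene differing gave a median of 4750 calls by the count test, where 4768 were observed. Both tests together called a median of 2173 simulated genes, a count 76.01% as large as the 2859 observed. Background alone may thus give a count of this order. The percent compares counts and not the same genes, and simulated and observed log2 fold changes had a median correlation of 0.44. Among genes far above background the simulation gave 644 calls where 840 were observed. It gave 0 changes over 2-fold where 21 were observed, 1 of which (Erdr1) the count test did not call. At 2-fold both tests together called 119 simulated against 215 observed genes at any level. Since all simulated genes had a common dispersion and the regions were independent, these values do not show what unequal regions would give. In VSVZ the same simulation gave a median of 2155 calls by the count test, where 2883 were observed. By both tests it gave 683 calls, a count 33.68% as large as the 2028 observed. Differences beyond background cannot be divided between genotype, plate row, animal and other differences between regions, because no row holds both genotypes. The regions varied in content too. Their mean striatal level (log2, background subtracted) ran from 2.72 to 6.88 in FlnKO VSVZ and from 2.77 to 6.31 in control VSVZ. Few independent animals or plate rows stay open in both tissues, with 3575 calls in cortex and 1 in VSVZ after counts were summed within plate row and group. The real split of regions gave 4768 calls in cortex and 2883 in VSVZ, the highest of the other splits 1003 and 0, and 1 of 100 splits in each tissue, the real one, reached the observed count. Such splits treat regions as independent, while some regions share an animal, so they cannot exclude chance among animals.

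Striatal neuron genes were higher in the heterotopia than in FlnKO cortex, with striatal tissue inside some regions and expression by heterotopia cells as candidate explanations. Of 16 heterotopia regions, 6 had over 75% of the 14 striatal genes above every FlnKO cortex region, 7 had under 25%, and 3 lay between, which is consistent with striatal tissue inside some regions. By the mean striatal level 9 regions were above the highest FlnKO cortex region, which does not separate expression by heterotopia cells (group FlnKO_PH) from neighbouring tissue. The mean striatal level was 3.22 in plate row A, 6.77 in row B, 4.61 in row C and 7.25 in row G, and VSVZ regions reached 6.88. For heterotopia against FlnKO cortex the real split gave 1681 calls and the highest of the others 1254, for heterotopia against FlnKO VSVZ 1675 and 580, and for the control tissues 3700 and 1, and 1 of 100 splits, the real one, reached each count.

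Cwc22 was lower in FlnKO than in control regions. Genotype as the whole cause is argued against by 9 control regions at or below the highest FlnKO region. Of the Cwc22 variance in control VSVZ, 97.26% lay between plate rows, a share that 1 of 6106 genes, Cwc22 itself, reached. This argues against a plate-row batch effect over all genes. Row F of control cortex argues against it too, with values from 11.9 to 21.5 and from 116 to 131. The background share of these row F regions was 64.4 to 66.7% in plate columns 1 to 3 and 51.0 to 55.5% in columns 9 to 12. A batch effect within a row was not tested. A copy number or strain difference between animals may account for the widest gap between neighbouring control values, 1.543 on the log2 scale between 30.5 and 88.9, but it cannot be told apart from other causes without a map of regions to animals. Of its neighbours within 1 Mb, 3 were tested and 1 was called lower, with a median log2 fold change of 0.10.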

How the results depend on the processing

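Tests chosen only after the data were seen are the background covariate, the plate rows left out in turn, summed counts with background subtraction, the control reference with background subtraction, the axis and list tests with background subtraction, and the genes far above background. Counts of calls are set here against 4768 and 2883 for genotype in cortex and VSVZ, 1681 and 1675 for the heterotopia against FlnKO cortex and VSVZ, 3700 for the control tissues and 575 for the difference test. DESeq2, limma-voom, upper quartile and total-count scaling and all groups in one fit left every one of the 6 counts within 1.5 times these values, from 396 to 5306. Of the 574 named-gene entries DESeq2 kept the direction and side of the threshold in 563, voom in 552, upper quartile scaling in 547, the random row block in 527, the authors' signals in 440 and background subtraction in 438, while summed counts weakened 305. Low counts limit genes near background, since most genes lie under the limit of quantification in every group, and 0 regions had a total under their group's median divided by 3, so no alternative without shallow regions gave a value.

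In cortex the genotype count was 14291 without a filter, 2396 with the stricter filter, 1 with the background covariate, 2587 with summed and background-subtracted counts and 840 among genes far above background (644 in regions simulated with no gene differing). In VSVZ it was 6575 and 1306 with these filters, 1885 with plate row as a random block, 1 with summed counts, 8 with the covariate, 0 with summed and subtracted counts (limma-trend, 1782 at an unadjusted p under 0.05, against 1 by edgeR on summed counts) and 375 among genes far above background (43 simulated). A fixed row block could not be fitted there. Heterotopia against FlnKO cortex gave 856 with the authors' signals, 4049 without a filter, 897 with the stricter filter, 668 with background subtracted, 808 with a fixed row block, 1 with summed counts, 24 with the covariate and 0 with summed and subtracted counts (limma-trend, 1263 at an unadjusted p under 0.05). Heterotopia against VSVZ gave 336 with summed counts, 308 with summed and subtracted counts and 3930 and 4056 with control VSVZ as the reference, on counts and with background subtracted. The control tissues gave 2217 with the stricter filter, 2405 with summed counts and 2147 with summed and subtracted counts. The difference test gave 79 with the authors' signals, 1131 without a filter, 165 with the stricter filter, 162 with background subtracted, 251 with a fixed row block, 29 with summed counts, 372 with the covariate and 3 with summed and subtracted counts. Fewer genes enter the stricter filter and more the fit without one, and fewer samples enter the summed counts. In cortex the background share does not overlap between genotypes, so the covariate can hardly be separated from genotype. For the rest the cause was not tested.

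Leaving out plate rows in turn gave from 482 (row B) to 2844 (row A) calls for the heterotopia against FlnKO cortex, with 823, 921 and 777 without rows C, D and G. It gave from 1105 (row C) to 1709 against VSVZ, from 385 to 896 (row B) for the difference test, from 4195 to 4632 and from 2149 to 3042 for genotype in cortex and VSVZ, and from 2671 to 3461 for the control tissues. With the replicate number as a block, heterotopia against FlnKO cortex gave 505 calls, and the other 5 counts stayed within 1.5 times. The numbers do not pair the regions, since mean correlations of same-numbered regions ran from −0.0336 to 0.159, and at most 3 regions of a comparison correlated best with their own number.

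Lists passing camera with an estimated correlation numbered 0 in 5 comparisons, against 8, 10, 12, 13 and 14 with the preset one, and 3 against 8 in the difference test. With background subtracted 3 passed in cortex and 3 in the difference test, and with an estimated correlation as well 0, 0, 3, 3, 2 and 0. Fry passed 19 lists for genotype in cortex and 22 for the control tissues. On the axis FlnKO cortex minus control cortex turned to −0.0263 with background subtracted.

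Named genes that turned direction in the cortex comparison, with log2 fold changes, were Fezf2 (0.30), Parm1 (0.26), Hs3st4 (0.35), Tac1 (0.12), Zbtb20 (0.0204), Tyms (0.19), Cldn11 (0.0022), Olig2 (0.23) and Dcc (0.13) with the authors' signals. They were Parm1 (0.10), Hs3st4 (0.11), Tac1 (0.0293), Zbtb20 (0.0255), Tyms (0.0626), Olig2 (0.16), Efnb3 (0.0490), Xbp1 (0.0369) and Flnb (0.16) without a filter. With background subtracted they were Fezf2 (0.31), Parm1 (0.40), Hs3st4 (0.56), Tac1 (0.25), Zbtb20 (0.0902), Tyms (0.20), Cldn11 (0.0511), Olig2 (0.32) and Dcc (0.26), and with a fixed row block Penk (0.30), Car2 (−0.0745) and Tuba1a (−0.12). In VSVZ they were Wfs1 (0.0611), Zbtb20 (0.0546), Cspg4 (0.0072) and Gabra3 (0.0111) without a filter. Against control cortex in place of FlnKO cortex the heterotopia values turned for Gm3893 (0.17), Osbpl1a (0.0945), Whrn (−0.27), Syn1 (0.0167), Grin2a (0.0118), Gria3 (0.16), Amigo2 (−0.43), Dlx5 (−0.28), Vim (−0.38), Aif1 (−0.40), C1qa (−0.0551), C1qc (−0.0757), Cfl1 (0.40), Map1b (0.29), Pafah1b1 (0.12), Kcnc1 (0.17), Scn8a (0.25), Gabrb2 (0.0399), Gabrb3 (0.18), Ndufs2 (0.47), Atp5o (0.28), Atp5b (0.56), Atp5a1 (0.55), Rpl4 (0.47) and Hsp90aa1 (0.36). Against control VSVZ they turned for Ncam1 (0.0524), Glul (0.19), Serpina3n (0.31) and Tuba1a (0.25). In the difference test Pou3f2 (−0.14) and Nedd4l (−0.26) turned with the authors' signals, and Pou3f2 (−0.34), Nedd4l (−0.59), Gabra4 (−0.0854) and Dnajb1 (−0.22) with background subtracted. Among the added alternatives the background covariate reversed 70 of the 574 entries, the control reference with background subtracted 19 and summed and subtracted counts 10, while plate rows left out in turn reversed 0. The cause was not tested for these genes.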

Other observations

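The comparisons of genes far above background and of Ttr by plate row were chosen only after the result was seen.

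Signals and further names are given here for genes far above background that changed over 2-fold, some of them already described. With background subtracted (limma-trend), the imprinted gene Ndn had a signal of 73.9 ± 26.9 in FlnKO cortex (SD, n = 13) against 32.7 ± 10.1 in control cortex (n = 16). The clock gene Nr1d1 and the protocadherin gene Pcdh10 rose by 1.08 and 1.03 there, and the RNA-binding protein gene Mbnl2 by 1.10. Fus rose from 57.2 ± 14.5 to 112 ± 14.9. Rara, Chmp1b and Hikeshi were lower. Rara fell from 948 ± 181 to 467 ± 107, Chmp1b, of the machinery that remodels membranes, fell by 1.27, and Hikeshi fell from 141 ± 23.6 to 48.5 ± 16.6. In VSVZ the G protein subunit gene Gng3 rose by 2.70 ± 0.55, the chemokine gene Cx3cl1 by 2.54 ± 0.63, the splicing regulator gene Rbfox1 by 2.14 and the imprinted gene Snrpn by 2.07, and Hikeshi fell by 1.30. Some regions share an animal, so p-values for these genes are too small. Erdr1 gave −2.06 ± 0.81 in cortex and −2.87 ± 0.86 in VSVZ with background subtracted, while edgeR gave 0.42 and 0.08 with adjusted p of 0.41 and 0.912.

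Ttr was above the FlnKO cortex regions in every heterotopia region, but not above all VSVZ regions. On the background-subtracted log2 scale heterotopia regions ran from 4.09 to 10.69, FlnKO cortex from 0.30 to 4.00, FlnKO VSVZ from 2.25 to 6.59 and control VSVZ from −0.12 to 5.05. By plate row the heterotopia averaged 8.53 in row A, 6.81 in row B, 8.07 in row C and 4.36 in row G, against 5.56, 3.57 and 4.90 in FlnKO VSVZ of rows B, C and G, so that in row G it was lower in the heterotopia. The row G heterotopia regions are those whose titles name no tissue. Kl, also on the choroid plexus list, was above the highest FlnKO cortex region in 10 of 16 heterotopia regions.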
